A study of Arabidopsis thaliana with 12 samples.

How the data were processed

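Roots and shoots of Arabidopsis seedlings of the wild type Wassilewskija-4 and of a line labelled aladin were measured on Affymetrix Arabidopsis Gene 1.0 ST arrays, with 3 arrays for each of 4 groups. Per the labels, seeds were stratified for 3 days and seedlings grown for 10 days on vertical plates with 1% sucrose and 1% agar under 16 h of light at 20 °C, and roots and shoots were separated and frozen at once. The authors deposited log2 values made with RMA, per the submitters' processing notes; the software, its version, the chip description and the level at which probes were summarised are not given in the sources used here. The scale was taken as log2 from RMA and from the range of the values. The table held 38408 probe sets and no missing values or detection calls, so no signal-based filter was applied in the main analysis, and the number of arrays limits the precision.

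Probe sets were linked to genes by the annotation table supplied for the array, whose build is not given in the sources used here. At least 1 gene was named for 17481 probe sets (exactly 1 for 16722, several for 759), and 20927 had no named gene and were left out of the main tests. Symbols and gene order came from the RefSeq annotation of assembly GCF_000001735.4 (TAIR10.1), in which 16574 of the single-gene probe sets were found by gene number and 148 were not. For 145 genes more than 1 probe set was measured, and each was tested on its own, so counts of genes passed are counts of probe sets. Of the 1336 and 518 that passed in root and shoot, 1268 and 500 were linked to exactly 1 gene. Of the 145 genes, 13 had a probe set past the threshold given below in root and 7 in shoot. In 12 and 6 of these another probe set of the gene did not pass, and none passed in opposite directions.

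Groups came from the sample titles. R 4.3.3 and limma 3.58.1 were used to fit group means to all 12 arrays (lmFit, eBayes), with contrasts for aladin minus wild type in root and in shoot, the difference of these effects, and wild-type root minus wild-type shoot. Values of p were adjusted by the Benjamini-Hochberg method over the 17481 genes, with a threshold of 0.05. The residual degrees of freedom were 8 and the prior ones 3.67. The main model held no block for the replicate numbers. Sets were tested with camera at a preset correlation of 0.01 and adjusted over the sets tested, and again with an estimated correlation and with fry. Camera compares a set with the other genes, whereas fry tests a set against no change, so their p values answer different questions.

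The model, the tests, the threshold, 25 gene lists with 424 entries, the rule for named genes and most alternatives were chosen before the data were examined. A linked probe set was found for 74 entries, and 4 lists reached the minimum of 5 measured members: nuclear pore complex, mRNA export, auxin response, and abscisic acid, cold and drought. The other lists were nuclear transport receptors and Ran, reactive oxygen and redox, mitotic cell cycle, DNA replication, cytokinin response, salicylic acid and defence, jasmonate, early wound and touch response, heat shock, unfolded protein response, iron deficiency, phosphate starvation, nitrate response, circadian clock and flowering, photosynthesis, flavonoid and anthocyanin, glucosinolate, root hair, endodermis and suberin, xylem secondary wall and stomatal lineage. The photosynthesis, root hair, endodermis, xylem and stomatal lists served as markers of cell types. A further 25 families, defined by symbol, were added after the annotation was seen and before any of them was tested, and their named members were chosen after their values were seen.

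The named genes were ALADIN; in each organ the 12 largest rises and 12 largest falls among genes past the threshold whose groups did not overlap, on probe sets with exactly 1 gene; up to 4 members of each list with the smallest p; the 5 highest and 5 lowest interaction effects; up to 3 marker genes per list between wild-type organs; and the 10 genes with the strongest evidence in both organs. The alternatives covered the empirical Bayes prior, dim probe sets, the probe sets tested, normalization, array weights, replicate blocks, a fit per organ, stricter thresholds, and leaving out each library in turn. The procedure was tested on simulated data with the same 17481 genes: changes of 1 log2 unit were recovered for 89.6% of genes in root and 97.0% in shoot, changes of 0.5 for 43.3% and 40.3%, and 1.90% and 1.86% of calls were false. For the interaction 6.45% of calls were false with changes planted in root, above the 5% aimed at, and 2.40% with changes planted in shoot. The simulated noise was normal, independent between genes and, for each gene, of equal spread in all 4 groups. These rates hold for such noise only, and not for a spread that differs between organs or for correlated genes. Python 3.11 and matplotlib 3.10.9 drew the figures.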

Results

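Transcript levels were measured in roots and shoots of Arabidopsis thaliana seedlings on 12 Affymetrix Arabidopsis Gene 1.0 ST arrays. The seedlings were 10 days old and belonged to the wild type, the accession Wassilewskija-4, or to a line labelled aladin, after the gene ALADIN (AT3G56900), which codes for a protein of the nuclear pore complex. The arrays formed 4 groups of 3, namely wild-type root, aladin root, wild-type shoot and aladin shoot, and each array is called a library here. The values were RMA signals on the log2 scale for 38408 probe sets, of which 17481 were linked to at least 1 named gene and were tested. The median signal per library lay between 5.86 and 6.0. Pearson's r across probe sets was 0.990 to 0.993 between libraries of the same root group, 0.983 to 0.987 within shoot groups and 0.873 to 0.893 between organs. For arrays, the number per group limits the precision. The errors given with log2 differences are standard errors from limma with 3 libraries per group, and p values are adjusted over the 17481 genes unless stated otherwise. For each gene limma used 1 estimate of the spread over all 4 groups. Its errors in root and shoot are therefore equal even where its spreads differ. CML38, for example, had an SE of 0.17 in both organs. Its SDs were 0.07 (wild type) and 0.06 (aladin) in root, and 0.41 and 0.19 in shoot. Where a gene varied more in shoot than in root, its shoot errors and p values are too small.

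ALADIN is the gene after which the mutant is labelled. Its signal was higher, not lower, in the libraries labelled aladin. In root the mean went from 8.39 ± 0.03 (SD, n = 3) in wild type to 12.69 ± 0.09 (SD, n = 3), a difference of 4.29 log2 units (SE 0.07, 19.6-fold, adjusted p = 1.9e-11). In shoot it went from 7.74 ± 0.05 (SD, n = 3) to 12.39 ± 0.03 (SD, n = 3), a difference of 4.65 (SE 0.07, 25.1-fold, adjusted p = 7.6e-12). All 6 libraries labelled aladin lay above the wild-type libraries of their organ. The difference between the organs did not pass the test (log2 difference -0.36, adjusted p = 0.124). The nearest measured gene on one side, AT3G56920, rose with it, by 3.16 in root (SE 0.17, adjusted p = 1.4e-06) and by 1.77 in shoot (SE 0.17, adjusted p = 3.1e-04). The labels do not give the site of the mutation relative to the probes. Because the mutated gene's own signal went against a loss of its transcript, every direction below is that of the libraries labelled aladin against those labelled wild type.

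**Figure D1:**
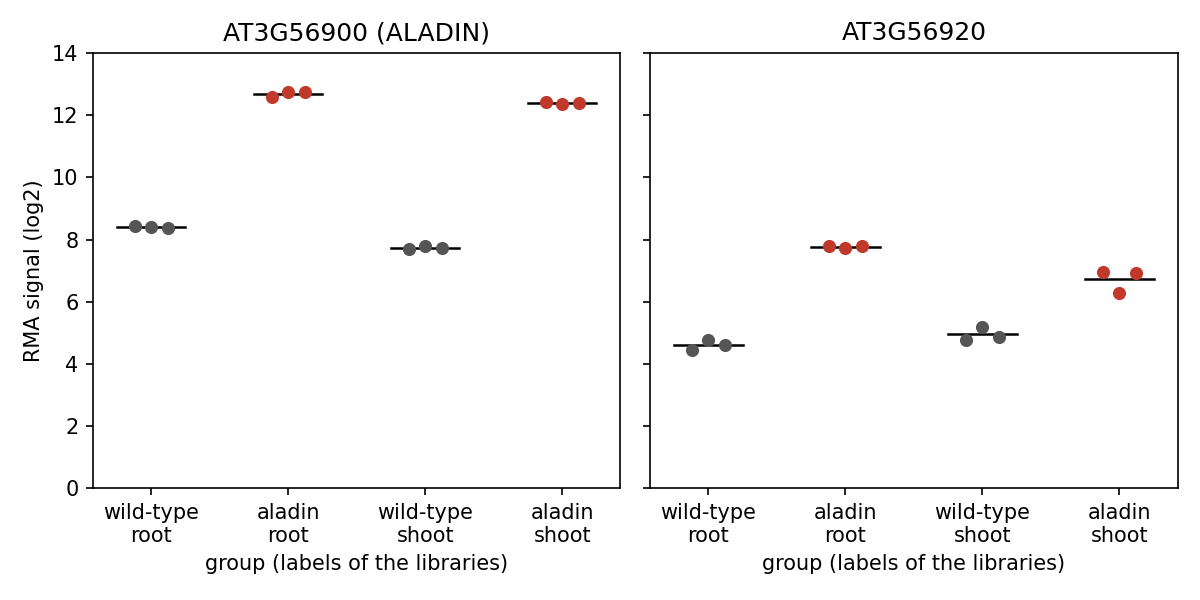
RMA signal (log2, vertical axis) of AT3G56900 (ALADIN) and AT3G56920 in each library of the 4 groups; points are libraries and lines are group means. ALADIN had means of 8.39 and 7.74 in wild-type root and shoot and of 12.69 and 12.39 in the libraries labelled aladin.

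The root comparison addressed which genes differ between the genotypes in root. In the root libraries labelled aladin, the largest rise was that of AT1G18830, for which the reference gives the synonym SEC31A, a coat protein of vesicles leaving the endoplasmic reticulum. It went from 4.59 to 9.22 (log2 difference 4.63, SE 0.13, adjusted p = 2.4e-09). CML38, a calmodulin-like protein, rose by 2.81 (SE 0.17, adjusted p = 2.4e-06), CCOAMT, a caffeoyl-CoA O-methyltransferase, by 2.76 (SE 0.36, adjusted p = 4.6e-04) and STZ, a zinc-finger transcription factor also named ZAT10, by 2.1 (SE 0.18, adjusted p = 2.7e-05). The largest fall was that of AT5G14650, from 9.14 to 4.41 (log2 difference -4.73, SE 0.21, adjusted p = 2.2e-07). EXPB2, a beta-expansin of the kind that loosens cell walls, fell by 1.81 (SE 0.17, adjusted p = 4.6e-05).

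The other genes among the largest root rises were AT5G42530 (3.06), AT5G03204 (2.92), AT5G57510 (2.68), AT4G29780 (2.60), AT4G05380 and AT4G27654 (2.51 each) and AT3G01175 (2.45). AT5G42530 is a shoot gene in these data, with a wild-type mean of 12.25 in shoot and 4.08 in root. The other large falls were AT3G22142 (-2.80), AT1G52820 (-2.55), AT4G12170 (-2.03), AT2G21260 (-1.87), AT3G46270 (-1.82), AT4G12545 (-1.79), AT2G33850 and AT1G14960 (-1.63 each), AT5G62210 (-1.55) and AT4G09110 (-1.54). In all, 1336 genes passed an adjusted p of 0.05 in root by limma, of which 809 were higher and 527 lower in the libraries labelled aladin, and 265 of the rises and 57 of the falls were at least 2-fold. Rises outnumbered falls under every setting, but hardly with array weights (1358 higher and 1342 lower). The 3 values of each group did not overlap for 31.7% of all tested genes, where chance gives 10%, and for 1332 of the 1336, which their small p values favour by selection. The count was 870 without aladin root replicate 2, 883 without wild-type root replicate 3 and 918 to 1026 without any other root library.

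Among the nuclear pore genes, 18 of the 32 listed were measured. In root 2 of the 18 rose, ALADIN and NUP98B (AT1G59660), the latter by 0.92 (SE 0.11, adjusted p = 2.0e-04). The other 16 did not pass, among them NUP85 (log2 difference 0.24) and NUP93B (0.15), and adjusted over the list alone the count was also 2. The median of the list was -0.01 while its mean was 0.28, and the set test did not pass with camera (adjusted p = 0.0899; adjusted p = 0.359 with an estimated correlation), but did with fry (adjusted p = 4.0e-06), ALADIN included. With ALADIN left out, the test gave an unadjusted camera p of 0.354 over 17 genes, as a choice made after the data were seen. The mRNA export genes (6 of 13 measured) held none past the threshold by limma, and 1 at an unadjusted p under 0.05 (camera adjusted p = 0.315). Of the nuclear transport receptors and Ran, 3 of 18 were measured and none passed by limma; XPO1B, an exportin, had a log2 difference of 0.27 (adjusted p = 0.127, and 0.0406 without aladin root replicate 3) and was the 1 gene that passed adjusted over the list alone.

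Hormone, stress and nutrient genes were measured in small numbers. The auxin response genes (7 of 19 measured) were higher as a set in root (camera adjusted p = 0.0067, median log2 difference 0.49), but not with an estimated correlation (adjusted p = 0.359 with an estimated correlation) or with fry (adjusted p = 0.0680). None of the 7 passed by limma over all genes, 3 had an unadjusted p under 0.05, and 3 passed adjusted over the list alone: GH3.3, an enzyme that conjugates auxin (1.27, adjusted p = 0.0555, and 0.0435 without wild-type shoot replicate 3 or 0.0326 without aladin shoot replicate 1), LBD16 (0.38, adjusted p = 0.0687, and 0.0366 without aladin root replicate 1) and GH3.1 (0.52). Both measured early wound and touch genes, CML38 and STZ, rose. BZIP60, a transcription factor of the unfolded protein response, rose by 0.85 (SE 0.14, adjusted p = 0.0020), while BIP1 (-0.48) and ERDJ3B (-0.27) did not pass over all genes, ERDJ3B being lower when adjusted over the list alone. SAG101, a partner of EDS1 in defence, rose by 0.51 (adjusted p = 0.0021) and was the only measured gene of 19 in the salicylic acid list. Of 4 measured iron deficiency genes, the IRON MAN peptide genes IMA1 (AT1G47400) and IMA2 (AT1G47395) rose, by 1.01 (adjusted p = 0.0033) and 0.66 (adjusted p = 0.0238). The IMA2 call ended without wild-type root replicate 1 (0.0918), wild-type root replicate 3 (0.0868), aladin root replicate 1 (0.0886) or aladin root replicate 2 (0.104).

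Falls in root were seen for KIN2, a cold-induced gene, by 0.76 (SE 0.13, adjusted p = 0.0034), the only one of 5 measured genes of the abscisic acid, cold and drought list to pass (camera adjusted p = 0.497). AUR1, an Aurora kinase of mitosis, fell by 0.42 (SE 0.08, adjusted p = 0.0071), and the other 2 measured mitotic genes, AUR2 (-0.15) and AUR3 (-0.18), did not pass. ARR15, a type-A cytokinin response regulator, fell by 1.00 (SE 0.24, adjusted p = 0.0253), and ARR16, named RR16 in the reference, had a difference of -0.45 that passed adjusted over the list alone. The ARR15 call ended without wild-type root replicate 1 (0.100), 2 (0.0606) or 3 (0.0664) and without aladin root replicate 2 (0.105) or 3 (0.0809). The counts adjusted over the list alone were otherwise those over all genes, except that LHCB4.2 and EXPA7 also passed as lower. The LHCB4.2 values of the 2 root groups overlapped. In 9 of the 16 lists with 1 to 4 measured genes none passed in root by limma over all genes: transport receptors, reactive oxygen and redox (4 measured, 2 at an unadjusted p under 0.05), DNA replication (1), jasmonate (1), heat shock (1), circadian clock and flowering (1), flavonoid and anthocyanin (3), root hair (2, with 1 at an unadjusted p under 0.05) and stomatal lineage (3). In the others of these 9, apart from XPO1B, 0 genes had an unadjusted p under 0.05. The remaining 5 lists, phosphate starvation, nitrate response, glucosinolate, endodermis and suberin, and xylem secondary wall, had 0 measured genes.

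Some genes of green tissue rose in the root libraries labelled aladin. Of 4 measured photosynthesis genes, RCA, Rubisco activase, rose by 0.61 (SE 0.10, adjusted p = 0.0031), whereas PORB (0.56), LHCB4.1 (0.13) and LHCB4.2 (-0.53) did not pass. Among gene families defined by symbol after the annotation was seen, the plastid-encoded NDH genes rose (9 of 10, median 0.51; camera adjusted p = 6.7e-12; adjusted p = 0.344 with an estimated correlation), with ndhD at 0.67 and ndhG at 0.54. The limma calls of ndhJ and ndhC each ended without any 1 of several libraries, among them wild-type root replicate 1 (adjusted p = 0.17 and 0.166). The plastid-encoded ribosomal and polymerase genes were higher as a set (9 of 17 rose, median 0.42; camera adjusted p = 2.4e-11; adjusted p = 0.344 with an estimated correlation), with rps19 and rpoC1 both at 0.79, and so were the plastid-encoded photosystem genes, with only 4 of 18 past the threshold (median 0.13; camera adjusted p = 6.4e-04; adjusted p = 0.585 with an estimated correlation), the 4 being psbN (0.71), psaC (0.63), psbM (0.53) and psaI (0.42). The family members named here and below were chosen after their values were seen. The WRKY transcription factors were higher as a set (camera adjusted p = 0.0041; adjusted p = 0.357 with an estimated correlation), with 2 of 7 past the threshold, WRKY41 by 1.89 (adjusted p = 2.1e-05) and WRKY29 by 0.43 (adjusted p = 0.0495). WRKY29 did not pass without any one of 10 of the 12 libraries, all but wild-type shoot replicate 1 and aladin root replicate 1 (adjusted p up to 0.181, without aladin root replicate 3). The other 21 families did not pass as sets in root (camera adjusted p from 0.154 to 0.922). Beside these rises, 144 nuclear genes at least 4 log2 units higher in shoot than in root, on the mean of both genotypes, had a median root difference of 0.32, a set chosen after the data were seen. Of these 39 rose, 104 did not pass and 1 fell, PSBY of photosystem II (-0.44, adjusted p = 0.0418).

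**Figure D2:**
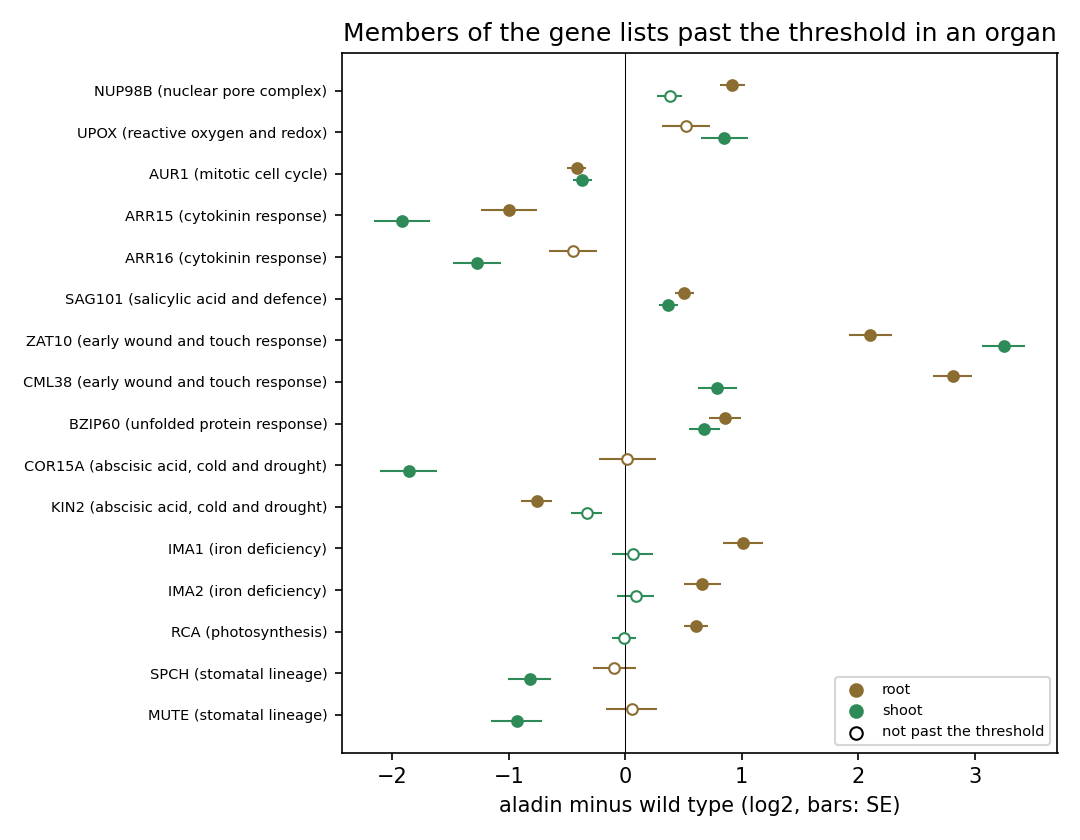
Log2 difference, libraries labelled aladin minus wild type (horizontal axis), with standard error bars, for the 16 genes of the gene lists other than ALADIN that passed the threshold in root or shoot; open points did not pass in that organ. ZAT10 (STZ) rose by 2.1 in root and 3.25 in shoot, and ARR15 fell by 1.00 in root and by 1.91 in shoot.

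The shoot comparison addressed the same question in shoot. After ALADIN, the largest rise in the shoot libraries labelled aladin was that of AT5G53230, from 4.88 to 8.53 (log2 difference 3.65, SE 0.23, adjusted p = 1.3e-05). STZ rose by 3.25 (SE 0.18, adjusted p = 7.5e-06), from 6.41 to 9.66, and AT5G53240, next to AT5G53230, by 2.70 (SE 0.20, adjusted p = 4.2e-05). COR15A, a cold-regulated chloroplast protein, fell by 1.86 (SE 0.24, adjusted p = 0.0023), from 11.86 to 10.00. ARR15 and ARR16 (RR16), the 2 measured cytokinin response genes, fell by 1.91 (SE 0.24, adjusted p = 0.0017) and by 1.27 (SE 0.21, adjusted p = 0.0082).

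Other large shoot rises were AT2G23321 (2.45), AT1G72920 (2.42), AT4G29780 (2.11), AT4G27657 (1.97), AT5G63130 (1.92), AT4G27652 (1.80) and AT3G56920 (1.77). UGT76B1, a glucosyltransferase, rose by 2.23 (SE 0.47, adjusted p = 0.0287), a call that ended without wild-type shoot replicate 2 (0.0877), wild-type shoot replicate 3 (0.0682), aladin shoot replicate 1 (0.0927) or aladin shoot replicate 3 (0.0829). The other large falls were AT2G18150 (-2.43), AT3G55240 (-1.96), AT3G60650 (-1.58), AT2G16660 (-1.54), XTH33, a xyloglucan endotransglucosylase (-1.39), AT3G05640 (-1.37), AT4G11190 (-1.32), AT4G15700 (-1.22) and the MADS-box gene AGL24 (-1.20). In all, 518 genes passed in shoot by limma, 261 higher and 257 lower in the libraries labelled aladin, with 76 rises and 18 falls of at least 2-fold. The balance turned to 397 higher and 465 lower with a trend and robust prior, to 317 and 344 with dim probe sets left out and to 177 and 193 without wild-type shoot replicate 3, while the 3 other scalings gave 288 and 217, 269 and 206, and 248 and 181. The groups did not overlap for 19.0% of all tested genes, where chance gives 10%, and for all of the 518, which their small p values favour by selection. A fit on the shoot libraries alone, with its own estimate of the spread and fewer degrees of freedom, gave 58 genes, 56 of them among the 518. Such a fit on the root libraries alone gave 1793, more than the 1336 of the main fit. Fewer degrees of freedom alone therefore do not account for the fall in shoot. Pearson's r within groups was lower in shoot (0.983 to 0.987) than in root (0.990 to 0.993). Estimated array weights were 0.641 to 0.808 for the shoot libraries and 0.944 to 2.45 for the root libraries. With these weights 202 genes passed in shoot and 2700 in root. Letting the spread differ between organs thus lowered the shoot count and raised the root count in both ways tried. The 518 of the main fit therefore rests on a spread shared with the less variable root libraries. In the main fit the shoot count was 282 without wild-type shoot replicate 2, 305 without aladin shoot replicate 1 and 293 without aladin shoot replicate 3.

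In shoot, the abscisic acid, cold and drought genes (5 of 19 measured) were lower as a set (camera adjusted p = 0.0226; adjusted p = 0.0897 with an estimated correlation), with a median of -0.33. Over all genes COR15A alone passed, while adjusted over the list alone 3 did, COR15A, COR15B (-0.69) and KIN2 (-0.33). COR15B was dim, at 3.35 in wild-type and 2.66 in aladin shoot, below the threshold of 4.375 used for dim probe sets. The KIN2 values of the 2 shoot groups overlapped. The set call ended without wild-type shoot replicate 3 (adjusted p = 0.103) and without aladin shoot replicate 3 (adjusted p = 0.0522), and with dim probe sets left out (adjusted p = 0.110), which left 3 of the 5 genes, fewer than the 5 set as the minimum. Over all settings the adjusted p ran from 1.0e-04 with fry, which asks a different question, to 0.110 with camera. In the nuclear pore list ALADIN alone passed (1 of 18), with NUP98B (0.38, adjusted p = 0.0823) also past when adjusted over the list alone; the set test gave a camera adjusted p = 0.201 (0.0489 without aladin shoot replicate 1) and fry an adjusted p = 5.9e-06, ALADIN included, and its median was -0.02 against a mean of 0.27. Of the mRNA export genes (camera adjusted p = 0.892) and the auxin response genes (camera adjusted p = 0.892) none passed by limma, with 0 and 1 at an unadjusted p under 0.05.

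The wound and touch genes STZ and CML38 both rose in shoot, CML38 by 0.79 (SE 0.17, adjusted p = 0.0296), which was lost without wild-type shoot replicate 1 (0.0501), aladin shoot replicate 1 (0.0907) or aladin shoot replicate 2 (0.0743). BZIP60 rose by 0.68 (adjusted p = 0.0238), lost without wild-type shoot replicate 2 (0.0640), aladin shoot replicate 1 (0.0569) or aladin shoot replicate 3 (0.0717). SPCH and MUTE, transcription factors of the stomatal lineage, fell by 0.82 (adjusted p = 0.0369) and 0.93 (adjusted p = 0.0437), whereas FAMA of the same lineage had a difference of -0.10 (adjusted p = 0.793). The SPCH call ended on leaving out any of the 6 shoot libraries, wild-type root replicate 2 or aladin root replicate 3 (adjusted p 0.0507 to 0.112), and the MUTE call on leaving out any library but aladin shoot replicate 3 (0.0542 to 0.128). SAG101 rose by 0.37 (adjusted p = 0.0333) and AUR1 fell by 0.37 (adjusted p = 0.0333). The SAG101 call ended without any library but wild-type shoot replicate 1 and aladin shoot replicate 2 (0.0503 to 0.0941). The AUR1 call ended without any library but wild-type shoot replicate 1 and the 3 aladin root libraries (0.0527 to 0.0998). UPOX (AT2G21640), a marker of oxidative stress in mitochondria, rose by 0.85 (adjusted p = 0.0477), a call that ended without any library but aladin shoot replicate 2 and aladin root replicates 1 and 3 (0.0595 to 0.133).

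Adjusted over the list alone, AUR2 (-0.25) and AUR3 (-0.38, adjusted p = 0.0587 over all genes, and 0.0498 without aladin root replicate 3) were also lower in shoot, as were DFR (-1.54, adjusted p = 0.103 over all genes, and 0.0203 without aladin shoot replicate 1) and UF3GT (-0.80) of anthocyanin synthesis, and XPO1B (0.28) was higher. In 9 lists with 1 to 4 measured genes none passed in shoot by limma over all genes: transport receptors (1 of 3 at an unadjusted p under 0.05), DNA replication, jasmonate, heat shock, iron deficiency, circadian clock, photosynthesis (0 each), flavonoid and anthocyanin (2 of 3) and root hair (1 of 2). Of the families, the plastid-encoded ribosomal and polymerase genes were higher in shoot (3 of 17, namely rps16 by 0.64, rpoC2 by 0.44 and rpoB by 0.42; camera adjusted p = 2.2e-04; adjusted p = 0.617 with an estimated correlation). The rpoC2 call ended without any library but wild-type shoot replicate 1 (up to 0.0954, without aladin shoot replicate 2), and that of rpoB without wild-type shoot replicate 2 (0.0698) or aladin shoot replicate 1 (0.0720), 2 (0.0601) or 3 (0.0726). The UDP-glycosyltransferases were also higher (3 of 51, namely UGT76B1, UGT73B5 by 1.32 and UGT73C1 by 1.09; camera adjusted p = 0.0112; adjusted p = 0.0900 with an estimated correlation), but not without aladin shoot replicate 1 (0.0994). The UGT73C1 call ended without any library but wild-type root replicate 1 and aladin shoot replicate 2 (up to 0.143, without aladin shoot replicate 3). The IQD proteins were lower as a set with none of 14 genes past the threshold by limma (camera adjusted p = 0.0470; adjusted p = 0.464 with an estimated correlation). That call was lost without wild-type shoot replicate 1 (0.0823), wild-type shoot replicate 2 (0.116), aladin shoot replicate 1 (0.126), aladin shoot replicate 3 (0.0686) or wild-type root replicate 3 (0.0517). The other 22 families did not pass as sets in shoot, the closest being the plastid-encoded NDH genes (median 0.10, camera adjusted p = 0.0551). These passed with each array centred on its median (0.0460) and without wild-type shoot replicate 3 (0.0262), wild-type root replicate 1 (0.0377) or wild-type root replicate 2 (0.0400), and had an adjusted p = 0.847 with an estimated correlation. The plastid-encoded photosystem genes (camera adjusted p = 0.121) passed without wild-type shoot replicate 3 (0.0262).

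The question whether the genotypes differ alike in both organs was addressed across genes. AR781 rose by 2.08 in root and 1.60 in shoot, PUB23, a ubiquitin ligase, by 1.48 and 1.54, AT1G23710 by 1.86 and 1.34, AT1G07135 by 2.24 and 1.67, AT4G05380 by 2.51 and 1.71, and AT5G66070 by 0.99 and 0.91, in the libraries labelled aladin. AT2G18150 fell by 1.47 in root and fell by 2.43 in shoot. With ALADIN, AT3G56920 and STZ, these are the 10 genes with the strongest evidence in both organs. Of 203 genes past the threshold in both, 129 were higher in both and 64 lower in both, where independence gives 12.1 and 7.75, and 10 went in opposite directions. Both calls use the same estimate of the spread of a gene, so they are not independent and these expected counts are too low. With a separate fit per organ, 58 genes passed in shoot and 38 in both organs with the same sign. Across genes, which are not independent replicates, Pearson's r of the log2 differences was 0.330 and Spearman's rho 0.233. Leaving out any 1 library lowered the 193 genes with the same sign in both organs. They numbered 123 (without aladin shoot replicate 1) to 179 (without aladin shoot replicate 2).

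**Figure D3:**
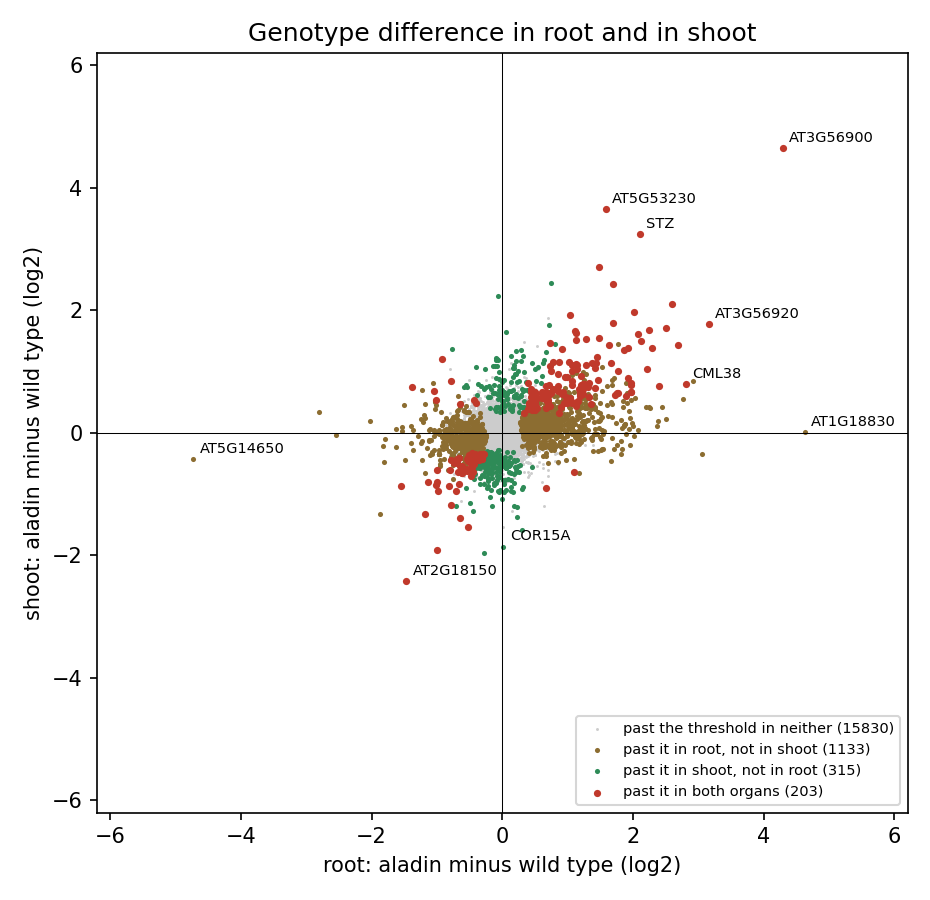
Log2 difference between the libraries labelled aladin and wild type in root (horizontal axis) and in shoot (vertical axis) for the 17481 tested genes, coloured by the organs in which they passed the threshold. The 203 genes past it in both organs lie mostly along the rising diagonal, with ALADIN (AT3G56900) at 4.29 and 4.65, while AT1G18830 stood at 4.63 in root and 0.01 in shoot.

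Whether the effect of genotype differed between the organs was tested as an interaction. AT1G18830 had the largest positive difference of effects, 4.62 (SE 0.18, adjusted p = 2.7e-07), since it rose in root and stood at 0.01 in shoot. AT5G42530 (3.41), AT4G27654 (2.28), AT2G36650 (2.26) and CCOAMT (2.21) followed. AT5G14650 had the largest negative difference, -4.30 (SE 0.30, adjusted p = 5.3e-05), followed by AT3G22142 (-3.15), AT1G52820 (-2.51), AT4G12170 (-2.22) and AT4G22470 (-2.14), of which AT4G22470 rose by 1.37 in shoot and had a root difference of -0.77 that did not pass. COR15A, which fell in shoot and stood at 0.02 in root, had a difference of 1.88 (adjusted p = 0.0164), whereas RCA (0.62, adjusted p = 0.0527), IMA1 (0.95, adjusted p = 0.0778), SPCH (0.73, adjusted p = 0.211), MUTE (0.99, adjusted p = 0.146) and UGT76B1 (-2.30, adjusted p = 0.114) did not pass. In total 375 genes passed by limma, 250 with the higher effect in root and 125 with the higher effect in shoot. The CCOAMT call was lost without any library but aladin shoot replicate 3 (adjusted p up to 0.115, without wild-type root replicate 2), and the count was 213, 235 and 211 without wild-type root replicates 1, 2 and 3, 220 without aladin root replicate 2 and 235 without aladin root replicate 3.

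The wild-type organs were compared to set the baseline of each organ's genes. RCA stood at 8.67 ± 0.06 (SD, n = 3) in root and 12.73 ± 0.05 (SD, n = 3) in shoot, PORB, an enzyme of chlorophyll synthesis, was lower in root by -5.38 log2 units and LHCB4.1, an antenna protein, by -2.96. The root hair expansins EXPA7 and EXPA18 were higher in root by 1.78 and 2.88. SPCH (-5.57), FAMA (-4.52) and MUTE (-2.48) of the stomatal lineage were lower in root. By limma 10279 genes passed, 5578 higher in root and 4701 higher in shoot, a balance that turned to 4966 and 5576 with each array centred on its median.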

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

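The tests of neighbouring genes, of the labels and of shoot tissue in the root libraries were chosen only after the results were seen; the tests on other splits and relabelings were written before.

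The effect of genotype differed between root and shoot for 375 genes by the interaction test, and those among the named genes are given here as root effect minus shoot effect in log2 units. Genes with the higher effect in root were AT1G18830 (4.62), AT5G42530 (3.41), AT4G27654 (2.28), AT2G36650 (2.26), CCOAMT (2.21), AT5G03204 (2.07), AT3G01175 (2.03), CML38 (2.02), AT3G56920 (1.39) and AT5G57510 (1.25). COR15A (1.88), AT3G60650 (1.88), AT3G55240 (1.68), AT3G05640 (1.59), AT4G15700 (1.44) and AT2G16660 (1.02) also had positive differences and had fallen in shoot. Negative differences were those of AT5G14650 (-4.30), AT3G22142 (-3.15), AT1G52820 (-2.51), AT4G12170 (-2.22), AT4G12545 (-1.70), AT1G14960 (-1.69), AT3G46270 (-1.61), AT2G33850 (-1.40) and EXPB2 (-1.33), which had fallen in root. AT4G22470 (-2.14), AT5G53230 (-2.06), AT2G23321 (-1.70), AT5G53240 (-1.21) and STZ (-1.15) had the higher effect in shoot. The interaction call of CCOAMT ended without any 1 of 11 of the 12 libraries (adjusted p up to 0.115, without wild-type root replicate 2). So did those of AT5G57510 (up to 0.108, without aladin root replicate 3) and STZ (up to 0.111, without aladin root replicate 2), also for 11 libraries each. For 9 libraries each, removal ended the calls of AT5G53240 (up to 0.125, without aladin root replicate 2) and AT3G55240 (up to 0.0769, without wild-type root replicate 2).

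Signal outside the tested genes was seen among the 20927 probe sets without a named gene. In a test adjusted over all 38408 probe sets 1032 of them passed in root (619 higher, 413 lower in the libraries labelled aladin) and 381 in shoot (216 higher, 165 lower), beside 1123 and 344 probe sets with a named gene.

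ALADIN was higher in the libraries labelled aladin in both organs. A single wrong genotype label or a swap of some libraries is excluded, since the lowest library labelled aladin lay 4.16 log2 units above the highest wild-type library in root and 4.56 in shoot. A chromosome segment of other origin that changes genes 6 to 30 places away is argued against by 2 of 50 such measured genes past the threshold in either organ (AT3G56770 and AT3G56790), where 93.5% of windows elsewhere held as many; a segment without effect on those genes was not tested. Of the 10 measured genes 1 to 5 places away 6 passed, as in 0.117% of windows, which transcription at the locus that also changes the genes next to it needs, but from which a chromosome segment of other origin no longer than 5 places on each side cannot be told apart; chosen after their values were seen, these include AT3G56920, AT3G56891 (-0.92 in root) and AT3G56890 (0.67 in shoot). All genotype labels exchanged cannot be told apart from an effect of the genotype, because 6 of 6 libraries labelled aladin lay above the wild type and the exchange is confounded with the groups; the genotype itself stays open as untested.

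The 144 shoot-enriched nuclear genes had a median difference of 0.315 in the root libraries labelled aladin, against -0.035 for all genes (39 rose, 1 fell and 104 did not pass; no set test was run), and 99 root-enriched genes had a median of 0.170 in the shoot libraries. Normalization over both organs together was not excluded. The root median was 0.327 after normalization within each organ, but that step was run on the deposited values. Their sorted values already lay within 0.283 of each other between any 2 arrays, so the step could change little and cannot undo an earlier joint normalization. Shoot tissue carried over into the aladin root libraries, if composed like the shoot libraries, is argued against as the whole cause for some plastid-encoded ribosomal and polymerase genes. These are the 6 at shoot levels that nuclear genes reach. Of them 5 rose more than the upper quartile of the nuclear share gives (median of the 6 0.51 against 0.0787), and rps18 (implied share 0.85%) did not. The median implied share of the 6 was 10.4% against -0.515% to 2.44% for the 4 nuclear genes at such levels. The comparison is small, since PSAE-1 (12.34) and HPR (12.30) among the 4 lay below all 6 in shoot. That leaves LHB1B2 (13.03) and PSBW (12.89), so carry-over with a saturated signal is not excluded here. Carry-over of shoot tissue stays open for the nuclear set (median implied share 0.751%, quartiles 0.159% and 1.3%; median rise 0.231 without aladin root replicate 1), though 23 of the 144 lay more than 2 SE below and 26 above the rise that this share gives, among the abundant ones LHB1B2 at -0.14 against 0.18 and AT1G74470 at -0.44 against 0.17. It stays open for the plastid-encoded NDH genes too, where 10 of 10 exceeded the share (median 0.51 against 0.0597) but at shoot levels 0.917 below the highest value of an array, so that a saturated signal cannot be told apart, and where a test added after that one found 8 of 18 photosystem genes below the rise that the NDH share gives (median 0.13 against 0.33); the genotype stays open as untested.

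Among the 10 splits of the libraries of an organ, too few for a share under 0.05, the count of genes was as large in 1 of 10 in root (1336; highest other 0), in 1 of 10 in shoot (518; highest other 3) and in 1 of 10 between the wild-type organs (10279; highest other 0). The count of lists was as large in 4 of 10 splits in root (1; highest other 1) and in 4 of 10 in shoot (1; highest other 2), and the count of families in 4 of 10 in root (4; highest other 6) and in 1 of 10 in shoot (3; highest other 2). With the labels exchanged within both organs, 7 of 100 relabelings gave as many interaction genes as the real 375 (highest other 631); the 6 others all kept the real split of the root libraries and with it the root effect, so chance was not excluded and these relabelings do not decide on it. For genes past the threshold in both organs with the same sign, 1 of 100 relabelings gave as many as the real 193 (highest other 1). That argues only against labels that are arbitrary in both organs at once, and it does not decide for either organ alone, where 10 splits are too few. Since other splits gave almost no genes in either organ, it does not test whether the organs agree.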

How the results depend on the processing

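The settings for families, for the nuclear pore list without ALADIN and for set medians under other scalings were chosen only after seeing the data; the others were chosen before the data were examined. No named gene result reversed under any setting; of 179 gene results 95 were past the threshold, 61 of them under every setting, and of the 84 others 69 were past it under none. ALADIN kept its call and direction throughout (4.26 to 4.35 in root and 4.63 to 4.68 in shoot on leaving out 1 library). A prior with a mean-variance trend and robust hyperparameters, changed together, gave 862 genes in shoot (518 before), 594 for the interaction (375 before) and 342 in both organs with the same sign (193 before). With all probe sets tested, more of them than before by construction, 2155 passed in root (1336 before) and 20311 between wild-type organs (10279 before). A fit on the compared libraries only gave 1793 in root (987 higher, 806 lower), 58 in shoot (40 higher, 18 lower) and 38 in both organs. Array weights gave 2700 in root, 202 in shoot and 118 in both. Testing against a fold of 1.5 left, by construction, 181 in root, 27 in shoot, 41 for the interaction, 3906 between wild-type organs and 13 in both, and an adjusted p under 0.01 left 709, 126, 125 for the interaction and 65 in both. Of the lists, 0 passed in root with an estimated correlation (1 before), and with fry the nuclear pore list passed in place of the auxin list; in shoot 0 passed with an estimated correlation, 2 with fry and 0 with dim probe sets left out (1 before), where the abscisic acid, cold and drought list was tested on 3 of its 5 genes. Leaving out 1 library gave 870 to 1415 genes in root, 282 to 460 in shoot, 211 to 374 for the interaction, 123 to 179 in both organs, 9238 to 10354 between wild-type organs, 1 list throughout in root and 0 to 2 lists in shoot (0 without wild-type shoot replicate 3 or aladin shoot replicate 3, and 2 without aladin shoot replicate 1). Under the 3 other scalings each list and family that had passed with camera still passed in the same direction, and the plastid-encoded NDH genes also passed in shoot under 1 of them. Apart from settings that test more probe sets, set a stricter threshold or leave out libraries, the cause was not tested. Array weights and the fit per organ, which let the spread differ between organs, both raised the root count and lowered the shoot count. Whether replicate numbers mark pairs was not settled. Residuals of same-numbered libraries of different groups correlated at -0.0568 to 0.0971 (mean 0.0165), and those of different-numbered ones at -0.0966 to 0.0851 (mean -0.00823). Of the 12 libraries 6 correlated best with their own number. The replicate block within organ gave 209 genes in shoot, 242 for the interaction and 96 in both organs; the block across all groups gave 1237 in root, 379 in shoot and 312 for the interaction, and plants as a random block gave 1339, 518 and 363. No detection calls were used here, so how far dim genes lie above background limits what can be said of them.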

Other observations

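The test of neighbouring genes was chosen only after the results were seen. The genes in the next 2 paragraphs were chosen after their values were seen, from families defined by symbol.

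Genes of the cell wall went both ways in root. Of 23 expansin and expansin-like genes, EXLA1 (1.04) and EXLA3 (0.83) rose in the libraries labelled aladin, while 5 fell, EXPB2 (-1.81), EXLA2 (-0.76), EXPA4 (-0.53), EXPB3 (-0.53) and EXPA15 (-0.33) (camera adjusted p = 0.154 for the family). The EXPB3 call ended without wild-type root replicate 1 (0.0539), wild-type root replicate 3 (0.0624) or aladin root replicate 3 (0.0701), and that of EXPA15 without any library but aladin shoot replicates 1 and 2 (up to 0.193, without wild-type root replicate 3). XTH29, of the xyloglucan endotransglucosylases, rose by 1.40 (adjusted p = 1.1e-04), whereas XTH32 fell by 0.68 and XTH33 by 0.65 (camera adjusted p = 0.672). In shoot EXPA9 fell by 0.92 (adjusted p = 0.0016; interaction 1.22, adjusted p = 0.0023).

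Among sugar transporters and signalling peptides, SWEET11 rose in root by 1.12 (adjusted p = 1.1e-05; interaction 1.28, adjusted p = 2.8e-04), while SWEET1 fell in shoot by 0.83 (adjusted p = 0.0042). CLE41 and CLE44, which code for peptides that act in the vascular cambium, rose in root by 0.61 (adjusted p = 8.2e-04) and 0.87 (adjusted p = 0.0014), and the MADS-box gene AGL42 fell in root by 1.23 (adjusted p = 5.6e-05). The beta-glucosidase genes BGLU45 and BGLU46 rose in root by 1.06 and 1.07. As families none of these passed in root (camera adjusted p = 0.193 for SWEET, 0.457 for CLE, 0.667 for AGAMOUS-like and 0.550 for beta-glucosidases).

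A hypothesis was that neighbouring genes change together more often than the arrangement of calls by chance. With the surroundings of ALADIN left out, 102 neighbouring pairs in root passed in the same direction (74 higher, 28 lower), such as BGLU45 with BGLU46, against a mean of 45.5 and a highest count of 72 in 10000 permutations (permutation p = 1e-04, the smallest possible). The count was 58, 54 and 50 without wild-type root replicates 1, 2 and 3 and 65, 52 and 53 without aladin root replicates 1, 2 and 3, each above the highest permuted count of its own fit (39 to 48). In shoot 8 pairs did, such as AT5G53230 with AT5G53240, against a mean of 6.92 and a highest of 19 (permutation p = 0.4). That result changed with single libraries: the count was 16 without aladin shoot replicate 2 (permutation p = 5e-04), 9 without wild-type shoot replicate 3 (permutation p = 0.01) and 6 without wild-type shoot replicate 2 (permutation p = 0.03). It was 4 without wild-type shoot replicate 1 or wild-type root replicate 3, and 5 without aladin shoot replicate 1, aladin shoot replicate 3, wild-type root replicate 2 or any aladin root library (permutation p 0.07 to 0.7), so no statement on shoot rests on it. Whether probes shared by related neighbours raise the counts was not tested.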
